A study of Mus musculus with 4 samples.

How the data were processed

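Single-cell RNA was measured with the 10x 5' chemistry, per the labels' protocols, in CD45-positive, YFP-positive cells sorted from tumor and spleen of mice with a Cx3cr1-Cre driver. There were 2 libraries, each holding cells of both tissues with 6 antibody hashtags. The first came from mice with MC38 tumors. The second was assigned to mice with B16F10 tumors from the series' design text, since its own title does not name the tumor. Each library has a deposited matrix of UMI counts (unique molecular identifiers, whole numbers per gene and cell barcode) with the hashtag counts in the same matrix, and a deposited table that gives the tissue of each hashtag. Per the submitters' processing notes, the counts were made with Cell Ranger on the mm10 genome, version 6.0.0 for the MC38 library and 4.0.0 for the B16F10 library. The annotation release and the cell calling settings are not given in the sources used here. No cell type annotation and no map from hashtags to animals was used here. Both matrices listed the same 32285 gene IDs, of which 32158 were found in GENCODE release M21.

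Hashtags 1, 2 and 3 marked spleen and hashtags 4, 5 and 6 marked tumor in both libraries, per the deposited hashtag tables. They are called spleen 1 to 3 and tumor 1 to 3 below. The series' design text says that both tissues came from the same mice, but nothing says whether a hashtag stands for a mouse, or which spleen and tumor hashtags share a mouse. The p-values therefore measure the spread between hashtag-labelled samples, which may be technical. Pairs of hashtags of the same tissue were compared in mononuclear phagocytes, and their counts differed by more than counting error in every pair (chi-squared per degree of freedom from 1.61 to 9.07). Sums over unlike cells can exceed counting error in any split, so this does not tell animals from technical samples.

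Hashtags were called with HTODemux in Seurat 5.3.0 (R 4.3.3) at a positive quantile of 0.99, after centered log-ratio normalization of each hashtag over cells. The wording fixed before the data were examined can also be read as normalization within each cell. That reading was run earlier, while the data were explored, and is kept as an alternative; the choice between the readings was thus made with its calls known. Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept. This left 7719 of 7899 barcodes in the MC38 library and 7355 of 7499 in the B16F10 library. Hashtag doublets (784 and 322 cells) were removed. Scrublet, run on each library, called 1 cell and 2 cells, which is too few for it to have worked, so doublets with the same hashtag remained. The spleen hashtags were shallow: over all barcodes of the MC38 library they held 870, 2645 and 1714 UMIs, against 33691, 104690 and 29035 for the tumor hashtags. The B16F10 spleen hashtags held 9469, 5462 and 7323 UMIs, against 28619, 78240 and 68341. A singlet's own hashtag had a median of 2 UMIs for each MC38 spleen hashtag, against 14, 39 and 12 for the tumor hashtags. In B16F10 these medians were 6, 4 and 5 against 41, 45 and 56. With so few UMIs, miscalled cells among the spleen singlets are not excluded. The summed gene UMIs of the 6 hashtags were 752549, 3095886, 2294527, 14416087, 13689022 and 13904969 in the MC38 library and 6536902, 4242884, 4167102, 4834986, 13831051 and 8879229 in the B16F10 library. Cells without a call (1698 and 1865) entered no comparison of tissues. Between classes, and between clusters of a class, the share without a call varied widely, so it can shift the class shares.

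Cells were clustered per library with scanpy 1.11.5 (Python 3.11.15): counts scaled per cell and log-transformed, 2000 variable genes, 30 principal components, 15 neighbors, Leiden resolution 1. Pf4, Cxcl9, Cxcl10 and Cx3cr1 were left out of the variable genes and of the naming markers. A marker counted for a cluster when it was at least 2-fold above the median of clusters (with 20 CPM added) and found in at least 25% of its cells. A cluster took the name of the type with the largest share of its markers so counted. This needed at least 3 markers, a share of at least 0.5, a lead of at least 0.2 over every other lineage, and no other lineage at a share of 0.6 or more. Its 10 highest genes also had to hold at least as many markers of its own lineage as of any other, and a very shallow cluster without any of them stayed unnamed. T cell clusters were called regulatory or CD8 where at least 80% of those markers counted with Foxp3 or Cd8a at least 2-fold up. The markers were fixed before the data were examined, apart from leaving out Pf4, which had been a macrophage and platelet marker. The naming rule and each of its limits were settled after the clusters, their genes and their tissues were seen, with an eye to the names that would result. An earlier rule, the 50 genes highest against all other cells, had failed for tumor monocytes and macrophages and was dropped. The class comparisons below rest on these names. Unnamed clusters held on average 17.0% of spleen and 4.54% of tumor cells per hashtag in the MC38 library, and 5.79% and 1.41% in the B16F10 library. In the MC38 library the largest of them were cluster 16 (dendritic genes such as H2-DMb2 and H2-Oa, 9.26% of spleen cells), cluster 11 (Cd209a with Cd7 and Klrd1, 5.76% of spleen cells) and cluster 3 (T cell and macrophage genes together, 3.70% of tumor cells). In the B16F10 library cluster 14 was the largest, with 4.32% of spleen cells. Named clusters were pooled into mononuclear phagocytes (macrophage-like, red pulp macrophage-like, classical and nonclassical monocyte-like), dendritic, T, NK and B cells. Such rebuilt names may differ from those of the submitters.

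For each class and library, UMIs were summed per hashtag with at least 10 cells of the class. Tumor was tested against spleen with edgeR 4.0.16's quasi-likelihood test on these counts, with TMM scaling, filterByExpr's default filter and Benjamini-Hochberg adjustment. A gene is said to have risen or fallen where its adjusted p was under 0.05. Classes needed 50 singlets in each tissue, so B cells and neutrophils were not tested. In MC38 NK and dendritic cells only 2 spleen hashtags had enough cells. CPM, the usual unit for a gene's UMIs relative to all UMIs of a sum, is given as mean ± SD over hashtags. Where a gene had no UMI in a tissue, the fold is a lower bound against a floor of 3 UMIs over all cells of that tissue. Where it had 1 to 3 UMIs, the ratio of pooled CPM is given with an exact 95% counting interval. Intervals and floors cover counting error alone. Differences between the models were tested only as the interaction of tissue and library in a single edgeR fit of both libraries, because tumor model, library and Cell Ranger version cannot be separated. Class shares were compared per hashtag with exact two-sided permutation tests, and shares of cells carry exact 95% binomial intervals. To compare shares of cells with a UMI across depths, cells were also thinned to 2000 UMIs.

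A total of 20 gene lists with 230 symbols was fixed before the data were examined, and 4 of these symbols were not among the matrix symbols, with Cxcl11, Mx1 and Mx2 among them. The lists were tested with camera (limma 3.58.1, preset correlation 0.01) and fry on the same fits. The named genes follow a rule also fixed before the data were examined: Pf4, Cxcl9, Cxcl10, Cxcl11 and Cx3cr1; the 10 genes highest and the 10 lowest by log2 fold change in mononuclear phagocytes (5 each way in other classes) among called genes with at least 50 CPM in the higher tissue and no overlap of hashtags between the tissues; and up to 4 members of each list with the highest CPM. Predicted genes, mitochondrial, ribosomal, hemoglobin, immunoglobulin and T cell receptor segment genes, Xist and Y-linked genes were left out of that ranking only. Cxcl11 was not tested. Of the named genes, 2 are not reported here as single genes, but stay in the gene lists and in the counts of all genes.

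Before use, the fits were tested on simulated data drawn from the fitted means, dispersions and depths, with 200 genes changed per class. The share of 2-fold changes recovered was 58% and 76% in mononuclear phagocytes of MC38 and B16F10 (10384 and 8956 genes), 51% and 64% in T cells, 26% and 64% in NK cells, and 43% and 76% in dendritic cells. Of the 4-fold changes, 85% and 94% were recovered in mononuclear phagocytes and 72% and 87% in NK cells, and false calls made up 3.82% to 9.2% of all calls over the 8 simulations. A gene list raised 2-fold was called in each, with 1 further list called in B16F10 NK cells. Genes were drawn independently, so this does not test camera's preset correlation. As many genes were raised as lowered, and fewer than were called in the real data, so the shares of false calls may not carry over.

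The alternatives fixed before the data were examined were a hashtag rule of at least 10 UMIs and 80% of a cell's hashtag UMIs, a looser cell filter (200 genes, 20% mitochondrial UMIs), removal of hashtag doublets only, Leiden resolutions 0.5 and 2, thinned cells, cells with a platelet gene UMI left out, no filter on low counts, DESeq2 1.42.0, and leaving out each hashtag in turn. Further alternatives were chosen after seeing the data: centered log-ratio normalization within cells, a hashtag rule of at least 2 UMIs, removal of the top 5% of Scrublet scores, classical monocyte-like clusters alone, spleen singlets in clusters with over 90% tumor singlets left out, scaling by total UMIs, and camera with an estimated correlation.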

Results

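CD45-positive cells with the YFP label of Cx3cr1-Cre mice were compared between tumor and spleen in 2 tumor models, MC38 colon adenocarcinoma and B16F10 melanoma. After filtering, a hashtag gave a tissue to 1372 spleen and 3865 tumor cells of the MC38 library, and to 2730 spleen and 2436 tumor cells of the B16F10 library. Tumor cells were deeper, with a median of 9887 against 3719.5 UMIs per cell in the MC38 library and 9571.5 against 4681.5 in the B16F10 library. Each tissue had 3 hashtags per library, and the 3 MC38 spleen hashtags held 142, 701 and 529 cells. A further 1698 and 1865 cells had no hashtag call. Among the classes with over 100 cells, they were most common among B cells (59.2% without a call in the MC38 library, 40.6% in the B16F10 library) and NK cells (43.5% and 53.3%). Among mononuclear phagocytes they made up 17.8% and 17.7%, but unevenly over clusters. In macrophage-like cluster 2 of each library, 503 of 510 MC38 and 520 of 521 B16F10 cells were called tumor. Monocyte-like clusters of the spleen lost far more. Of 623 cells in MC38 cluster 6, 223 were called spleen and 16 tumor, and of 394 in cluster 13, 151 and 11. For B16F10 clusters 12 (552 cells) and 4 (330 cells) these were 264 and 42, and 200 and 16.

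Mononuclear phagocytes, that is monocyte-like and macrophage-like cells, were the largest labelled class in both tumors. They averaged 77.7 ± 2.04% of MC38 tumor cells against 31.5 ± 8.0% of MC38 spleen cells (mean ± SD over 3 hashtags). In the B16F10 library the shares were 56.3 ± 6.23% and 18.1 ± 0.979%. Macrophage-like clusters, named by genes such as C1qa and Apoe, held 71.8% of MC38 tumor cells and 1.65% of spleen cells, and 37.0% of B16F10 tumor cells and 0% of spleen cells. Nonclassical monocyte-like cells, named by Ace, Treml4 and Cd300e, averaged 12.4% of spleen and 0.286% of tumor cells in MC38 and 7.35% and 0.724% in B16F10. Classical monocyte-like cells, named by Ly6c2 and Ccr2, averaged 16.5% of spleen and 5.61% of tumor cells in MC38, but 9.63% and 18.5% in B16F10. The genes that name these subsets also differed between the tissues, so the shares of the broad class are the safer ones. B cells averaged 14.7 ± 6.18% of MC38 and 36.9 ± 5.42% of B16F10 spleen cells, against 0.207% and 1.05% of tumor cells. T cells averaged 27.9 ± 1.67% of spleen and 12.6 ± 2.13% of tumor cells in MC38, and 16.3% and 19.3% in B16F10. Dendritic cells averaged 3.28 ± 1.05% and 2.01 ± 0.522% in MC38 and 14.6% and 14.5% in B16F10. The MC38 share leaves out unnamed cluster 16, with 9.26% of spleen cells. Its top genes, such as H2-DMb2, H2-Oa and Asb2, were also top genes of a B16F10 cluster named cDC2-like. The contrast of dendritic shares between the libraries therefore depends on the naming rule. With 3 hashtags per tissue the smallest possible exact permutation p was 0.1, or 0.16 (MC38) and 0.2 (B16F10) after adjustment, so no share could pass a threshold of 0.05.

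**Figure D1:**
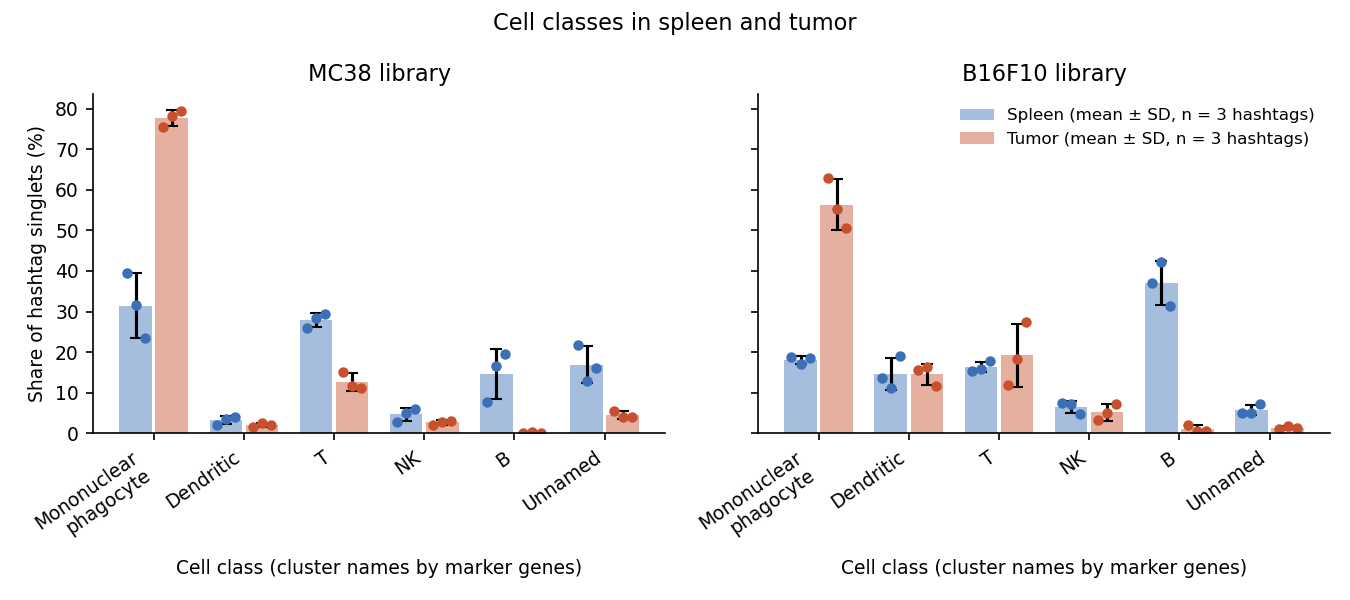
Shares of cell classes among hashtag singlets of spleen and tumor in the MC38 and B16F10 libraries. Bars show the mean and SD over 3 hashtags per tissue and dots show single hashtags; cells without a hashtag call are left out.

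Pf4, which encodes the chemokine CXCL4 (platelet factor 4), was found almost only in tumor macrophage-like cells. In MC38 mononuclear phagocytes it had no UMI in 401 spleen cells (median 4756 UMIs per cell) and averaged 79.6 ± 6.20 CPM in tumor, at least 51.4-fold higher (edgeR adjusted p 1.4e-10). In B16F10 it averaged 0.628 ± 0.584 CPM in spleen (2 UMIs in 496 cells) and 493 ± 181 CPM in tumor. That was a 706-fold ratio of pooled CPM with a 95% counting interval from 195 to 5833 (edgeR log2 fold change 9.75, SE 0.456, adjusted p 1.1e-09). All 3 tumor hashtags exceeded all 3 spleen hashtags in both libraries. At least 1 Pf4 UMI was seen in 28.0% of MC38 tumor mononuclear phagocytes (95% interval 26.4 to 29.7%; 842 of 3003 cells) and in 26.2% of those of B16F10 (23.9 to 28.7%; 353 of 1345 cells). After thinning to 2000 UMIs the shares were 9.12% and 16.2%. The same share was 0.820% and 1.22% in tumor T cells and 0.943% and 0.752% in tumor NK cells, before thinning. Tumor macrophage-like cells alone averaged 83.0 ± 7.01 CPM in MC38 and 637 CPM in B16F10. Classical monocyte-like cells of MC38 held no Pf4 UMI in either tissue (223 spleen and 217 tumor cells). In B16F10 they held 1 UMI in spleen and 23 in tumor, 20 of the latter in a single hashtag. Spleen red pulp macrophage-like cells had none in 11 MC38 and 32 B16F10 cells. The MC38 floor of 128 CPM lay above the 83.0 CPM of tumor macrophage-like cells. A level like that of tumor is therefore not excluded in these MC38 spleen cells. The B16F10 floor of 34.4 CPM leaves a low level open. Ppbp, the neighbouring platelet chemokine, averaged 0.149 ± 0.259 CPM in MC38 and 16.5 ± 25 CPM in B16F10 tumor mononuclear phagocytes.

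**Figure D2:**
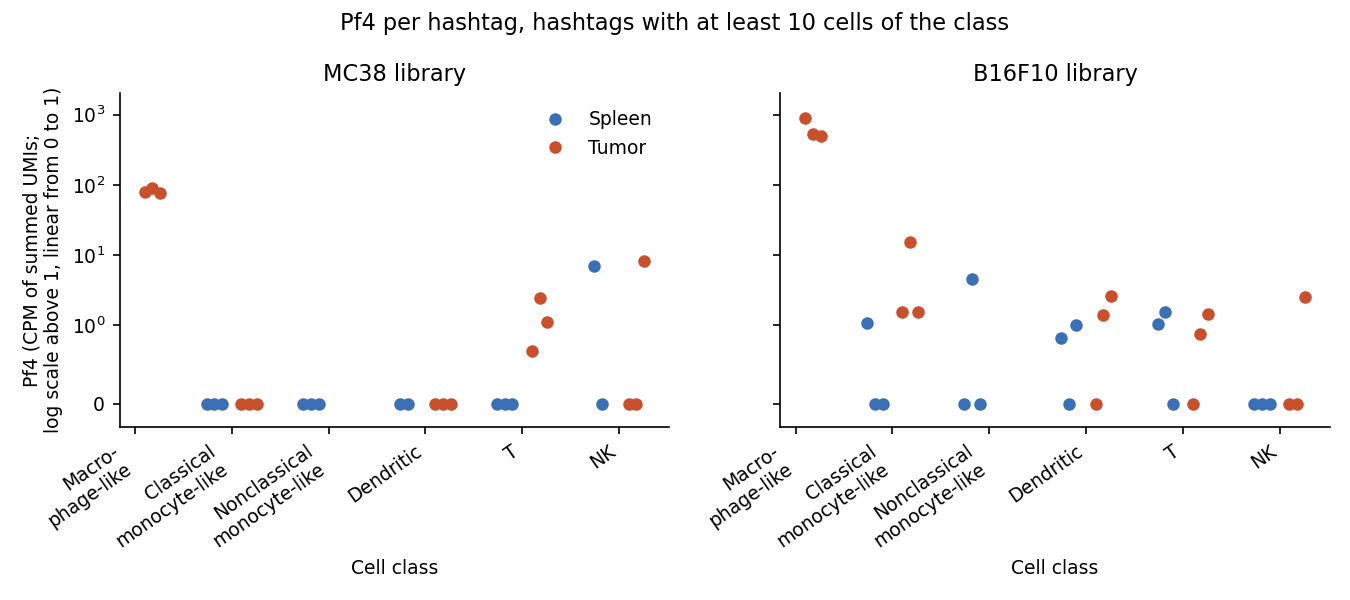
Pf4 in named cell classes of spleen and tumor, in CPM of each hashtag's summed cells. Dots are hashtags with at least 10 cells of the class; the axis is linear near 0 and logarithmic above.

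Mononuclear phagocytes of MC38 tumors differed from those of the spleen in many single genes, among them chemokines and genes of nonclassical monocytes. The 2 tissues held different clusters: in tumor 8 macrophage-like and 1 classical monocyte-like cluster dominated, and in spleen 1 classical and 1 nonclassical monocyte-like cluster. Of 10529 genes tested, 2803 were higher and 2068 lower in tumor, and 6250 had no overlap between the hashtags of the tissues, where chance alone would give 10%. Ccl7, a monocyte attractant, and H2-M2, a nonclassical class I molecule, had no spleen UMI and were at least 102-fold and 41.7-fold higher. Several further genes had only 1 or 2 spleen UMIs, so that ratios of pooled CPM carry wide 95% counting intervals. These were Vegfa, an angiogenic factor (793-fold, 142 to 31341), Arg1, which degrades arginine (576-fold, 159 to 4752), Ccl8, a monocyte attractant (475-fold, 131 to 3922), Dab2, an endocytic adaptor (293-fold, 52.6 to 11576), and Acod1, which makes itaconate (217-fold, 38.9 to 8564). AA467197 and Zmynd15 belonged to the same group (774-fold, 139 to 30556, and 285-fold, 79.0 to 2357). The largest falls were those of Ear2, from 244 to 3.62 CPM (log2 fold change -5.62), Hpgd, which degrades prostaglandins (-5.57), S1pr5, a receptor for egress (-5.49), and Ace, from 477 to 9.93 CPM (-5.17). Pglyrp1 (-5.11), Nxpe4 (-5.08), Adgre4 (-5.05), Serpinb2 (-4.80), Ccdc88c (-4.63) and BC035044 (-4.39) followed. Ear2, Ace, Pglyrp1 and Adgre4 also name the nonclassical monocyte-like cluster. With Pf4, these were the 20 genes ranked by the rule for named genes, which asks for a call and for hashtags of the tissues that do not overlap. The largest adjusted p among them was 4.6e-07 (Ccl7), and SEs ranged from 0.125 (Ace) to 1.295 (Ccl7).

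The CXCR3 ligands Cxcl9 and Cxcl10, which interferon-gamma induces, were higher in MC38 tumor mononuclear phagocytes. Cxcl9 rose from 52.6 ± 75 to 1338 ± 51.8 CPM (5.14, SE 0.369, adjusted p 1.8e-09). Cxcl10 rose from 95.1 ± 141 to 503 ± 94.7 CPM (2.80, adjusted p 3.9e-05), but DESeq2 did not call it (adjusted p 0.0838). A single macrophage-like cell of spleen 3 held 68 of the 93 spleen UMIs of Cxcl9 and 140 of the 174 of Cxcl10. Without spleen 3 the log2 fold changes were 7.41 and 5.01, so their size depends on that hashtag. Cx3cr1, the driver gene of the label, fell slightly from 268 ± 47.2 to 171 ± 5.17 CPM (-0.30, SE 0.102, adjusted p 0.0232), a call that several settings did not keep. Other chemokines rose as well: Cxcl2, a neutrophil attractant (6.77), Cxcl16, the ligand of CXCR6 (5.55), and Ccl5 (3.40), whereas Ccl6 fell (-1.75). Macrophage genes with a role in naming were up, with Apoe at 13565 against 1627 CPM (3.47) and complement C1qb, C1qc and C1qa at 5.63, 5.44 and 5.42. Il1b (4.41), its antagonist Il1rn (5.34), Osm (6.54), the matrix gene Thbs1 (7.08) and the protease Mmp14 (5.47) rose, and Fn1 fell (-1.29). Interferon-stimulated Isg15 (3.02), Bst2 (2.43) and Irf7 (1.49) were higher. So were class II genes H2-Eb1 (3.55), H2-Ab1 (3.47), H2-Aa (2.95) and Cd74 (2.81), and class I genes H2-K1 (1.39), B2m (1.15), Psmb8 (0.94) and H2-D1 (0.72). The glycolytic genes Ldha (2.46), Gapdh (2.24), Pgam1 (2.09) and Pkm (1.56) and the iron store gene Fth1 (2.75) rose too.

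In B16F10 tumors the mononuclear phagocytes showed a related program, with chemokines, Arg1 and matrix genes higher in tumor. Here tumor cells lay in 2 macrophage-like clusters and 1 classical monocyte-like cluster, and spleen cells in other classical and nonclassical monocyte-like clusters. Of 9122 genes tested, 2498 were higher and 2321 lower in tumor, and 5843 had no overlap between the hashtags, against 10% by chance. No spleen UMI was seen for Cxcl3, a neutrophil attractant, Mmp12, the macrophage elastase, or Dab2, which were at least 370.2-fold, 349-fold and 274-fold higher. The same held for AA467197 (at least 127-fold), Acod1 (at least 114-fold) and Pmp22 (at least 76.2-fold). Arg1 had 1 spleen UMI and reached 1012 ± 223 CPM in tumor, a pooled ratio of 2858 (95% counting interval 513 to 112880). Ccl7 rose from 1.91 to 1451 CPM (9.80), Spp1, which encodes osteopontin, from 3.83 to 2854 CPM (9.79), and Ccl2 by 7.34. The largest falls were in Slc12a2, an ion transporter (-4.34), S1pr5 (-3.82), Hpgd (-3.71), Pglyrp1 (-3.69), Calhm2 (-3.56), BC035044 (-3.49), Cd300e and Nxpe4 (-3.43 each), Il16 (-3.41) and Nfe2 (-3.33). Of these genes and Pf4, Acod1 had the largest adjusted p, 1.6e-06, and SEs lay between 0.140 (Spp1) and 0.987 (Acod1).

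Cxcl9 rose in B16F10 from 1.57 ± 1.75 to 463 ± 59.7 CPM (8.71, SE 0.304, adjusted p 7.5e-11) and Cxcl10 from 93.1 ± 31.3 to 496 ± 174 CPM (2.76, SE 0.262, adjusted p 1.1e-06). Cx3cr1 fell from 242 ± 47.2 to 43.9 ± 19.6 CPM (-2.13, SE 0.245, adjusted p 7.2e-06). Il1rn (6.12), Ptgs2, which makes prostaglandins (6.35), Thbs1 (5.50), Cxcl2 (4.92), Il1b (4.46) and Fabp5, a lipid carrier (4.40), rose, as did C1qb (4.06), C1qa (3.84) and C1qc (3.62). Ccl6 rose (1.89) and Fn1 rose slightly (0.45), both opposite to MC38. In classical monocyte-like cells alone this opposition was not kept: Fn1 fell in B16F10 (-0.41), Ccl6 did not change in MC38 (0.16), and neither difference between the models was called (0.31, adjusted p 0.516 for Ccl6; -0.34, adjusted p 0.577 for Fn1). Apoe did not change (0.16, adjusted p 0.598). The glycolytic genes Ldha (2.71), Gapdh (2.40), Pkm (1.95) and Eno1 (1.81) rose as in MC38. Class II genes H2-Eb1 (2.07), H2-Aa (1.67) and Cd74 (1.37) rose, while of the class I genes H2-D1 (-0.11, adjusted p 0.307) and H2-K1 (0.20, adjusted p 0.155) did not change. Isg15 rose (1.87), but Irf7 (-0.06, adjusted p 0.766) did not. Scaling by total UMIs in place of TMM moved the median log2 fold change of all genes by -0.41 in MC38 and -0.31 in B16F10, and the higher genes then made up 29.5% and 30.2% of all called genes, against 57.5% and 51.8%. The balance of higher and lower genes therefore depended on the scaling.

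Of the fixed gene lists, 14 were called higher and 1 lower in tumor mononuclear phagocytes of each library by camera with its preset correlation. With a correlation estimated from the values no list stayed called in MC38 (adjusted p 0.137 for each of the 15 lists), and 4 stayed in B16F10. Those 4 were hypoxia and glycolysis (17 of 17 tested genes higher; preset adjusted p 5.3e-11, estimated 0.0229), other chemokines (14 of 15; 6.9e-11, estimated 0.0229), tumor-associated macrophage genes (16 higher and 1 lower of 18; 1.8e-08, estimated 0.0229) and matrix and protease genes (9 of 9; 4.2e-06, estimated 0.0325). In MC38 the same lists had 16 of 16, 13 of 15, 16 of 18 and 8 of 9 genes higher (preset 3.9e-07, 4.0e-04, 2.2e-06 and 7.4e-04, estimated 0.137). The nonclassical monocyte list was lower with 11 of 11 genes in both libraries (1.3e-08 and 1.2e-07; estimated 0.137 and 0.131); all of its genes but Cx3cr1 also name a cluster. All 3 tested genes of the list of PF4 and CXCR3 ligands were higher in both (0.0122 and 0.00366; estimated 0.137 and 0.131). Interferon-stimulated genes were higher for 17 of 18 in MC38 (1.0e-06, estimated 0.137), and in B16F10 for 6, with 1 lower (0.0466, estimated 0.567). For class I presentation 9 of 9 genes were higher in MC38 (1.3e-04, estimated 0.137), and 4 of 9 in B16F10, where the list was not called (0.185). No difference of a list between the libraries was tested. For H2-K1, H2-D1, B2m, Psmb8, Irf7, Bst2 and Isg15 the interaction was not called in classical monocyte-like cells alone. Class II presentation had 8 of 8 and 7 of 8 genes higher (9.2e-06 and 0.00164; estimated 0.137 and 0.232). In classical monocyte-like cells alone, class II presentation had 1 higher and 1 lower of 8 genes in MC38 and 0 and 1 of 8 in B16F10 and was not called (0.637 and 0.564). The nonclassical monocyte list had 2 higher and 4 lower of 9 and of 10 genes there and lost its call too (0.0718 and 0.397).

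Complement genes were higher for 9 of 10 in MC38 and 8 of 10 in B16F10, with 1 lower in each (7.4e-04 and 4.4e-04; estimated 0.137 and 0.0636). Inflammatory cytokines had 10 of 12 genes higher in both (1.3e-04 and 6.4e-06; estimated 0.137 and 0.0779). Lipid handling and lysosome genes were higher for 10 and lower for 2 of 15 in MC38 and for 12 and 1 in B16F10 (0.00950 and 1.1e-05; estimated 0.137 and 0.0779). Cell cycle genes were higher for 14 of 15 and 10 of 11, with 1 lower in each (2.2e-06 and 0.00264; estimated 0.137 and 0.332), but with the top Scrublet scores removed the MC38 list turned down and was not called (adjusted p 0.692). Dissociation stress genes were higher for 13 of 15 and 10 of 15 (8.2e-05 and 0.00264; estimated 0.137 and 0.232), each with 1 lower. The Th1-Treg list had 4 of 5 and 2 of 2 genes higher (0.0190 and 0.0293; estimated 0.137 and 0.147). T cell exhaustion genes, with Entpd1 (2.91 and 2.12) and Havcr2 (1.84 and 0.73), had 3 of 4 and 2 of 2 higher (0.0904, not called, and 0.0438; estimated 0.174 and 0.251). Not called were iron and heme handling (6 higher and 2 lower of 10, against 7 and 2; 0.0987 and 0.0512) and cytotoxicity (0.191 and 0.434). Only 1 platelet gene, Clec1b in MC38, had enough UMIs for a test and did not change (-0.81, adjusted p 0.387), and no hemoglobin gene had. Adjusting over each list alone gave the same counts in both libraries, apart from 7 in place of 6 higher iron genes in MC38.

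**Figure D3:**
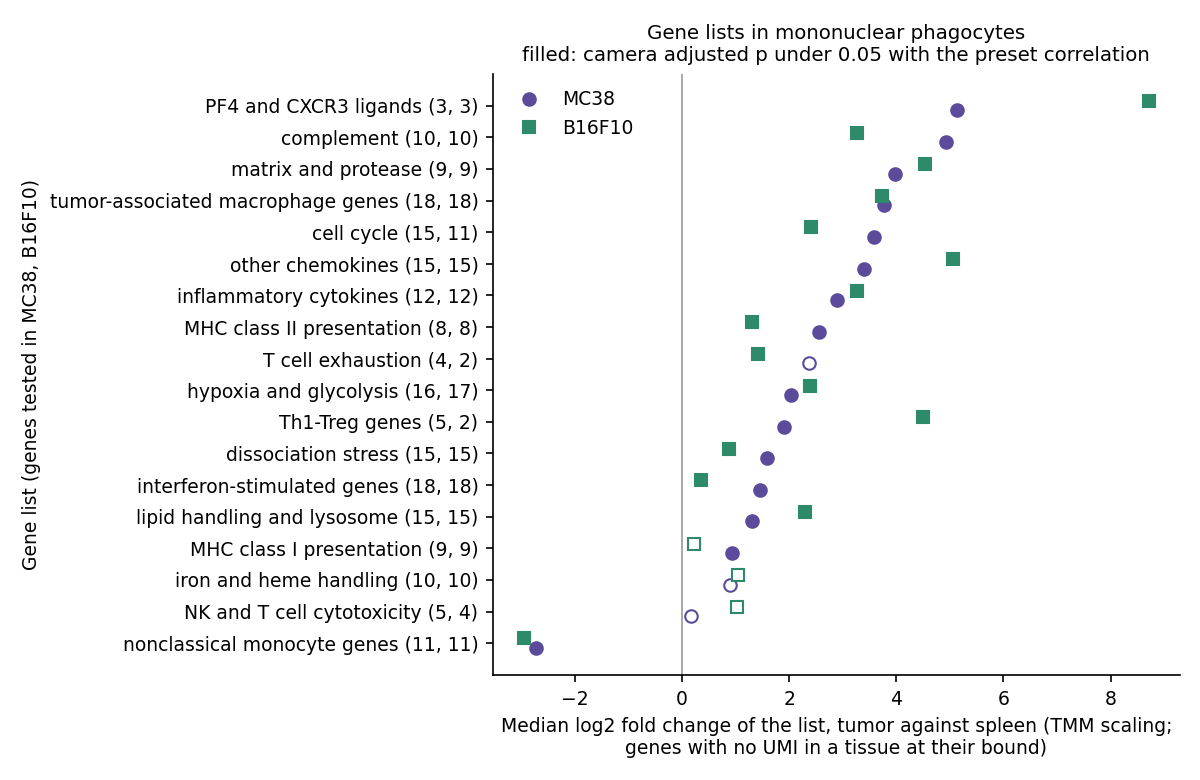
Median log2 fold change, tumor against spleen, of the fixed gene lists in mononuclear phagocytes of the MC38 and B16F10 libraries, with genes that have no UMI in a tissue set to their bound. Filled marks have a camera adjusted p under 0.05 with the preset correlation; numbers in brackets are the genes tested in each library.

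T cells of both tumors held more of several granzyme and checkpoint transcripts than spleen T cells. In MC38, tumor and spleen T cells lay mostly in different clusters. There 436 tumor cells formed a cluster without any spleen cell, and regulatory T-like cells were 107 spleen and 18 tumor cells. In B16F10 they were apart only in part. Clusters 8 (202 spleen and 2 tumor cells) and 17 (6 and 319) were apart, but cluster 18 held 204 and 134 and the regulatory T-like cluster 28 and 38. Of 6920 genes tested in MC38, 943 were higher and 691 lower in tumor; of 7333 in B16F10, 1616 were higher and 1515 lower. The MC38 count of lower genes was not stable, with 386 without spleen 2 and 362 by DESeq2. No overlap between hashtags was seen for 2846 and 3744 genes, against 10% by chance. Granzymes led the list. In MC38, Gzmf (at least 300.1-fold) and Gzmd (at least 72.4-fold) had no spleen UMI. In B16F10 the same held for Gzme (at least 86.4-fold) and Gzmf (at least 85.1-fold), while Gzmc had 1 UMI (pooled ratio 1280, 95% counting interval 230 to 50579). Gzmb rose from 53.5 to 1850 CPM in MC38 (5.23) and from 34.0 to 1466 CPM in B16F10 (5.48). The protease inhibitor Serpine2 (at least 47.9-fold), the metal binding Mt2 (at least 24.8-fold) and AA467197 (at least 35.8-fold) rose in MC38, and Mt1 (at least 143-fold) and Tff1 (at least 53.4-fold) in B16F10. Checkpoint genes rose in both: Pdcd1 (3.60 and 4.57), Ctla4 (2.82 and 4.60), Lag3 (2.17 and 4.37) and Tigit (0.96 and 3.59). The largest falls included Igfbp4, down 90.3-fold (95% counting interval 30.1 to 445) and 379-fold (129 to 1844) by pooled CPM, and Dtx1, a Notch pathway gene, with log2 fold changes of -5.45 and -4.98. Art2b (-4.64), Rflnb (-4.25) and Cmah (-3.88) fell in MC38, and Tmem108 (-6.13), Tdrp (-4.65) and Il6ra (-4.61) in B16F10. Among these top genes adjusted p was at most 0.000283 in MC38 (Gzmd) and 0.000483 in B16F10 (Gzme).

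Cxcr3, which encodes a receptor of CXCL9, CXCL10 and CXCL4, fell in tumor T cells of both libraries, from 226 to 48.6 CPM in MC38 (-2.07, adjusted p 1.5e-06) and from 124 to 52.7 CPM in B16F10 (-1.26). Tbx21, the Th1 regulator, rose (1.44 and 0.89), and Ikzf2, a Treg gene, fell in MC38 (-1.47) and rose in B16F10 (1.16). Cx3cr1 did not change in MC38 T cells (-0.15, adjusted p 0.826) and rose in those of B16F10 (1.90, adjusted p 0.00500). Ccl5 fell in MC38 (-1.26), and Ccl3 rose in B16F10 (2.81). The Th1-Treg list was called in neither library (3 higher and 3 lower of 7, adjusted p 0.834; 5 and 1 of 7, 0.0564). The exhaustion list was higher with 6 of 8 and 7 of 8 genes (6.0e-05 and 8.3e-06), but not called with an estimated correlation (0.135 and 0.131), and over the list alone 1 further MC38 gene was lower. Cytotoxicity genes were 7 higher and 1 lower of 10 in B16F10 (6.5e-04, estimated 0.301) and 6 and 1 of 10 in MC38 (0.0578, estimated 0.230), a difference between libraries that was not tested. Hypoxia and glycolysis genes were higher for 12 of 14 in MC38, or 13 over the list alone, and for 13 of 14 in B16F10 (3.5e-08 and 2.0e-06; estimated 0.135 and 0.301). Dissociation stress genes, which cell handling can induce, were higher for 13 of 15, with 1 lower, in MC38 and for 9, with 2 lower, in B16F10 (3.3e-08 and 0.0332; estimated 0.135 and 0.380). Macrophage transcripts such as C1qb (2.14) and Apoe (1.41) also rose in MC38 tumor T cells, so RNA of other cells in these sums is not excluded. Total-UMI scaling moved the median by -0.19 in MC38, with 38.9% in place of 57.7% of called genes higher, and by -0.01 in B16F10.

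NK cells of the tumors differed from those of the spleen in granzymes and had less Cxcr3. They also lay in different clusters, with 96 of the MC38 tumor and 119 of the B16F10 tumor NK cells in clusters with 3 and 0 spleen cells. Of 3815 genes tested in MC38, with 2 spleen hashtags, 407 were higher and 209 lower; of 3986 in B16F10, 457 were higher and 268 lower. The B16F10 count of lower genes hung on single hashtags, with 122 without tumor 3. In MC38, leaving out a spleen hashtag left only 1, so such counts are not used here and the stability of the MC38 counts cannot be judged. Hashtags did not overlap for 2007 and 1378 genes, against 20% and 10% by chance. In MC38 Gzmd (at least 94.7-fold), Gzmf (at least 92.7-fold), Spp1 (at least 78.4-fold) and Hilpda, a lipid droplet gene of hypoxia (at least 39.5-fold), had no spleen UMI. Gzmc rose to 7454 CPM from 2 spleen UMIs (pooled ratio 982, 95% counting interval 272 to 8106). Gzmb rose (2.86) and Gzma, which also names NK cells, fell from 6247 to 2182 CPM (-1.26). In B16F10 the heat shock genes Hspa1a (pooled ratio 613, 110 to 24243) and Hspa1b (326, 111 to 1582), which handling can also induce, led the higher genes. Vegfa (115, 31.4 to 955), the TGF-beta target Pmepa1 (62.4, 10.8 to 2506) and Ctla4 (at least 24.0-fold) followed, and Gzmb rose from 767 to 1666 CPM (1.33). The cytokine receptor Il7r fell in both, by 64.6-fold in pooled CPM in MC38 (20.9 to 323) and by a log2 fold change of -3.69 in B16F10. Dtx1 fell by 139-fold (23.5 to 5628) and 37.5-fold (10.0 to 315). Asb2 had no MC38 tumor UMI (at least 21-fold lower), and Cma1 (-3.83) and Batf3 (-3.74) fell there, as did Tmem176b (-2.99) and S1pr5 (-2.86) in B16F10. Cxcr3 fell by log2 fold changes of -2.85 and -1.62, and Cx3cr1 by -1.74 in MC38 and 18.0-fold in pooled CPM in B16F10 (5.86 to 89.7). Ccl5 fell (-2.57 and -0.80) and Tigit rose (1.68 and 2.51). The largest adjusted p among the top genes was 0.00673 (MC38, Gzmf) and 0.000654 (B16F10, Tmem176b). Cytotoxicity genes as a list were not called (0.466 and 0.454), and hypoxia genes were higher for 6 of 11 and 6 of 9, or 7 and 9 over the list alone (2.8e-04 and 0.00220; estimated 0.340 and 0.515). Dissociation stress genes were higher for 6 of 13 and 7 of 14 (2.8e-04 and 0.00220; estimated 0.415 and 0.515). In MC38 all 9 tested tumor-associated macrophage genes, Spp1 among them, and 3 of 3 complement genes rose (4.6e-07 and 0.00498; estimated 0.340 for both), with C1qb at 4.07. In B16F10 3 of 3 tested tumor-associated macrophage genes rose (1.8e-04, estimated 0.181). RNA of macrophages or doublets is thus not excluded as a source of the higher genes in either library. With the top Scrublet scores removed, MC38 Apoe, higher before (2.41), turned to -1.42 (adjusted p 0.0736). Total-UMI scaling moved the median by -0.26 and -0.16, and higher genes were then 40.4% and 41.1% of the called ones, against 66.1% and 63.0%.

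Dendritic cells of the tumors and spleens differed in single genes and in the kinds of cell they held. In B16F10 the spleen cDC2-like cluster (316 cells) and the tumor cDC2-like cluster (215 cells) shared no cell, and in MC38 a mature cluster and a cluster named cDC1-like made up the class. Of the latter, 31 spleen cells held Xcr1, a cDC1 marker, at 284 CPM and no Mgl2, a cDC2 marker, but 65 tumor cells held them at 23.0 and 569 CPM (pooled values chosen after they were seen), so its name is not safe for tumor cells and the MC38 comparison is of unlike cells. Of 3013 genes tested in MC38, with 2 spleen hashtags, 472 were higher and 276 lower; of 8109 in B16F10, 1950 were higher and 1763 lower. The MC38 count of lower genes was not stable, with 677 with the top Scrublet scores removed, where 3 spleen hashtags entered the fit. Leaving out a spleen hashtag left only 1, so such counts are not used here. Hashtags did not overlap for 1654 and 4847 genes, against 20% and 10% by chance. Ccl17, a ligand of CCR4, and the lectin Mgl2 had no spleen UMI in MC38 (at least 56.8-fold and 55.9-fold) and 1 and 2 UMIs in B16F10 (pooled ratios 878, 157 to 34704, and 808, 223 to 6671). AA467197 had none in either (at least 66.6-fold and 227.5-fold). The decoy receptor Il1r2 (at least 102-fold), the urokinase receptor Plaur (at least 43.7-fold) and Cxcl10 (at least 41.6-fold) were higher in MC38, and Ramp3 (at least 206.5-fold) and Plet1 (at least 98.2-fold) in B16F10. Cxcl9 rose from 141 to 612 CPM in MC38 (2.23) and from 128 to 317 CPM in B16F10 (1.62), where Cxcl10 rose by 2.04. Cxcl16 rose in both (2.12 and 2.42). Mycl, a cDC1 transcription factor (at least 42.3-fold), and Plpp1 (at least 18.4-fold) had no MC38 tumor UMI, and Apol7c (-5.01), Gpr141b (-4.71) and Pdia5 (-4.30) fell. In B16F10 the cDC2 gene Clec4a4 fell 322-fold by pooled CPM (88.5 to 2669), Stra6l 215-fold (58.9 to 1788) and Adgrl3 208-fold (57.0 to 1729), and Dtx1 (-7.17) and Cd4 (-5.72) fell by log2 fold change. In these 20 genes the largest adjusted p was 0.000246 (Plpp1) in MC38 and 1.6e-05 (Plet1) in B16F10. Other chemokines were higher as a list, with 4 of 7 (5 over the list alone) and 7 of 8 genes (0.0129 and 5.1e-04), but not called with an estimated correlation (0.276 and 0.236). In MC38 6 of 6 complement and 7 of 9 tumor-associated macrophage genes also rose (3.0e-06 each; estimated 0.166 each), with C1qb up 93.0-fold by pooled CPM (31.7 to 452). In B16F10 3 of 3 complement genes rose (0.0407, estimated 0.267), as did 6 of 8 tumor-associated macrophage genes, with 2 lower (0.0515, not called). RNA of macrophages or doublets is therefore not excluded here either. Dissociation stress genes were higher for 12 of 15 in MC38 (1.9e-05, estimated 0.166) and not called in B16F10 (0.714). In B16F10 total-UMI scaling moved the median by -0.33, higher genes were 27.0% in place of 52.5% of the called ones, and H2-Aa (0.30, then -0.03) and H2-Eb1 (0.24, then -0.08) changed sign.

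The tumor to spleen ratios of mononuclear phagocytes had the same direction in both models for 97.6% of the 3316 genes called in both (95% interval 97.0 to 98.1%, which takes genes as independent), with 1784 higher, 1453 lower and 79 opposite. These genes were picked by their calls; over all 9072 genes tested in both the share was 79.9%. Independent lists would share 667 higher and 490 lower genes. The ratio differed between the models for 892 of 9691 genes, 383 higher and 509 lower in B16F10. The count was 538 without MC38 spleen 2, 396 with thinned cells and 41 in classical monocyte-like cells alone, where fewer genes were tested. Ccl6 differed most clearly among the named genes (B16F10 minus MC38 3.65, adjusted p 2.1e-13). The monocyte attractant Ccl2 (3.70), the lipid carrier Fabp5 (1.72), Lgals3 (1.29) and Fn1 (1.74) were relatively higher in B16F10 tumors. Apoe (-3.29), H2-Ab1 (-1.55), Irf7 (-1.55), Bst2 (-1.49), Cd74 (-1.43), H2-K1 (-1.18) and B2m (-0.76) were relatively higher in MC38 tumors. Cx3cr1 fell further in B16F10 (-1.83, adjusted p 5.7e-04). In classical monocyte-like cells alone none of these differences, from Ccl6 to Cx3cr1, was called: that of Apoe was -0.18, of Cx3cr1 -0.14 and of B2m -0.24, and those of Fn1 (-0.34), Bst2 (0.082) and Cd74 (0.039) changed sign. For Pf4 the difference could not be judged, since MC38 spleen had no UMI and its fold has only a lower bound. Cxcl9 (3.62, adjusted p 0.0963) was not called as different, nor was Cxcl10 with all cells (0.00, adjusted p 1). Cxcl10 was relatively higher in MC38 once stray spleen cells were left out (-2.43, adjusted p 0.00406). Each model was a single library with its own Cell Ranger version, so model and batch cannot be told apart.

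**Figure D4:**
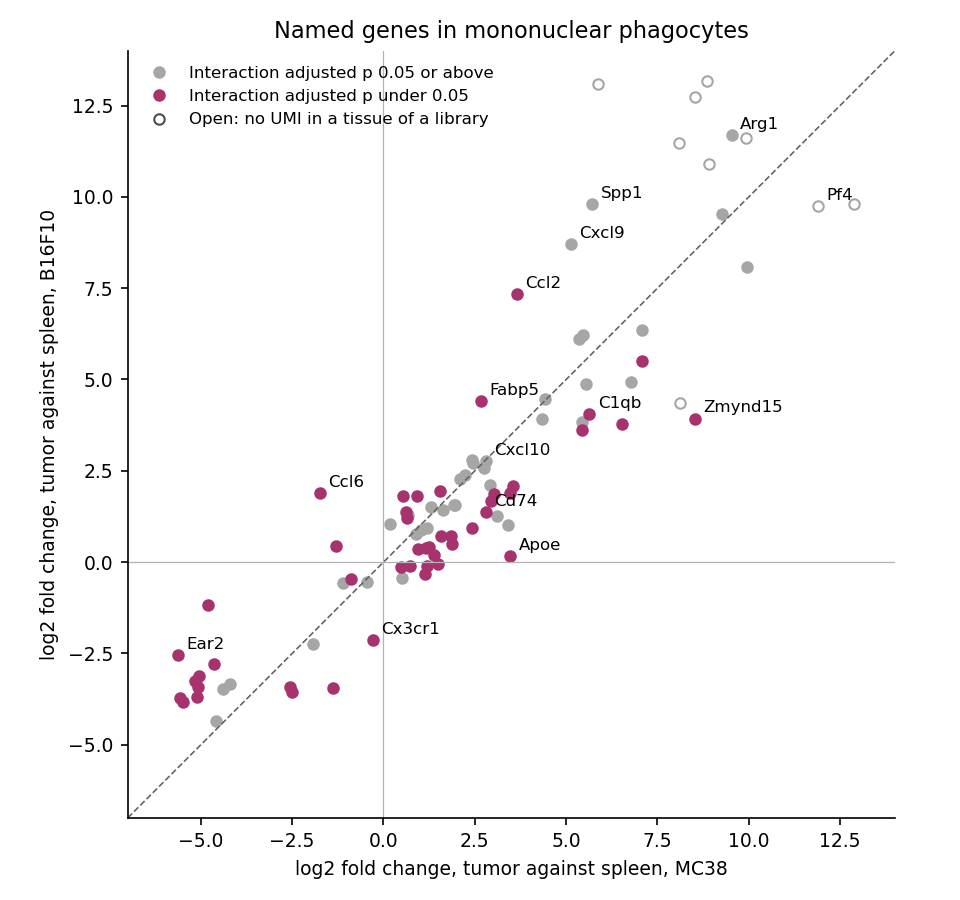
Log2 fold change, tumor against spleen, of named genes in mononuclear phagocytes of the MC38 and B16F10 libraries, 3 hashtags per tissue. Colored marks have an interaction adjusted p under 0.05, gray marks 0.05 or above, and the dashed line marks equal values. Open marks are genes with no UMI in a tissue of a library, whose fitted fold depends on the prior count.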

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

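The tests on free RNA, on the mix of clusters (for Pf4 and for the models) and on the kinds of splits were chosen after the result was seen; the platelet, doublet and other split tests were written down before their results were seen. In all, 48 results were picked out: 47 named genes whose tumor to spleen ratio in mononuclear phagocytes differed between the models by the interaction test, and a Pf4 signal in cells without a hashtag call.

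Of 97 named genes tested for that interaction, 47 differed, 19 with a higher and 28 with a lower log2 ratio in B16F10 (B16F10 minus MC38 throughout). Among chemokines and secreted factors these were Ccl2 (3.70), Ccl6 (3.65), Osm (-2.74), Fn1 (1.74) and Thbs1 (-1.56). Nonclassical monocyte genes and others that fell less in B16F10 were Serpinb2 (3.59), Ear2 (3.10), Ace and Adgre4 (1.94 each), Hpgd (1.87), Ccdc88c (1.82), S1pr5 (1.66), Nxpe4 (1.64), Pglyrp1 (1.45) and Nr4a1 (0.44). Cd300e (-2.02), Cx3cr1 (-1.83), Calhm2 (-1.05) and Il16 (-0.85) fell further in B16F10. Antigen presentation genes were lower in B16F10: H2-Ab1 (-1.55), H2-Eb1 (-1.46), Cd74 (-1.43), Ctss (-1.36), H2-Aa (-1.27), H2-K1 (-1.18), H2-D1 (-0.82), B2m (-0.76) and Psmb8 (-0.58). So were interferon-stimulated Irf7 (-1.55), Bst2 (-1.49) and Isg15 (-1.13), macrophage and complement genes Apoe (-3.29), C1qc (-1.79) and C1qb (-1.56), and Zmynd15 (-4.55), Trf (-1.43), Havcr2 (-1.11) and Npc2 (-0.81). The early response genes Fos (-1.31), Junb (-0.85) and Zfp36 (-0.60) were lower and Nfkbia (0.78) higher. Fabp5 (1.72), Lgals3 (1.29), Eno1 (0.89), Ftl1 (0.58) and Pkm (0.40) were higher. Of the 47 genes, 37 were called whichever hashtag was left out. Over all genes tested, 892 of 9691 differed. Many of the 97 genes were named for the largest changes in a single library. A smaller change in the other library, as for the genes that fell less or further in B16F10, is partly set by that choice.

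A different mix of clusters in the libraries is a possible account of this difference. In classical monocyte-like cells alone, the median difference of the called genes, taken in their direction, was 24.5% of that over all mononuclear phagocytes (0.248 against 1.01; 780 of the 892 genes tested there). This lies just under the bound of 25% set for that explanation, and picking genes by their size makes them shrink in any second look, so the margin is thin. A model difference confined to macrophage-like cells would shrink there as well, so the test cannot tell it from a different mix. Classical monocyte-like cells of the tissues also lay mostly in different clusters, so the mix is not held fixed there. The sign was kept by 74.2% of these genes, and 19 were called in both; of the 47 named genes only Osm (-4.15), Thbs1 (-3.09), Zfp36 (-0.79) and Junb (-0.64) were called in those cells. The model, the library and the Cell Ranger version cannot be told apart, and a biological difference between the tumors stays open and untested.

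Chance could not be excluded for the interaction by splits of the tissue labels within each library: 8 of 100 (drawn from 200) called at least the real 892 genes, and the highest other called 1975. The 7 others were all among the 19 drawn splits that keep or mirror the tissue labels of 1 library, and none of the rest reached 892, with a median of 0 over all. Such splits leave the whole tumor to spleen difference of a library in place, a structure of the samples. For the tissue comparisons 1 of 10 splits, the real one, reached the real count, with 0 genes in the highest other: 4871 genes in MC38 mononuclear phagocytes, 1634 in MC38 T cells, 4819 in B16F10 mononuclear phagocytes, 3131 in B16F10 T cells, 725 in B16F10 NK cells and 3713 in B16F10 dendritic cells. With 10 splits a share under 0.05 cannot be had.

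MC38 mononuclear phagocytes without a hashtag call, which no comparison used, held Pf4 at 2.20 CPM (8 UMIs in 6 cells), above the level of 0.826 CPM that a count of 0 allows there. Pf4 was thus weighed as a pattern, higher in tumor than in spleen phagocytes. Platelets stuck to cells would bring Ppbp at a like level, but by pooled CPM Ppbp reached 2.35% of Pf4 in tumor mononuclear phagocytes, the higher value of the 2 libraries, which argues against them as the whole source. Free RNA would reach all cells of a library, and each library pooled both tissues. Spleen mononuclear phagocytes held no Pf4 UMI in 401 MC38 cells and 2 in 496 B16F10 cells. Pf4 in tumor T or NK cells was at most 3.9% of that in tumor mononuclear phagocytes, a value that rests on 3 UMIs. The rise lay mostly in macrophage-like clusters, which held 1.65% of MC38 and 0% of B16F10 spleen cells. Tumor classical monocyte-like cells held Pf4 at 0% (MC38) and 1.52% (B16F10) of the level over all tumor mononuclear phagocytes. Whether like cells also differed between the tissues stays open. In classical monocyte-like cells the log2 fold change was 3.74 in B16F10 (edgeR without a filter, adjusted p 0.00108), mostly from a single hashtag, and MC38 had no UMI in them. A macrophage type that only tumors hold is the biological candidate and was not tested further.

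MC38 cluster 3, with T cell and macrophage genes in the same cells, may consist of doublets that share a hashtag. It held 133 tumor singlets with both kinds of UMI, 1.6 times the 83.0 expected from the 166 of 272 cells with 2 tumor hashtags that had both kinds, within the bound of 2 times set before. Its median of 15918 UMIs exceeded that of tumor T cells (5780.5) and macrophage-like cells (11045). Counted over all MC38 tumor singlets, 231 had both kinds, 2.78 times the expected number, so not every such cell is accounted for. The cluster stayed unnamed and entered no comparison.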

How the results depend on the processing

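The alternatives named as added in the methods were chosen after seeing the data, and the cause of a change was not tested unless stated. No paired analysis was possible because nothing pairs spleen with tumor hashtags, so the animal block was not run. The rule of 10 hashtag UMIs left too few cells for any MC38 fit and for B16F10 NK cells, and resolution 0.5 gave no MC38 dendritic fit. Removing hashtag doublets only left the same number of MC38 cells, so there it tests nothing. Leaving out stray spleen cells left the B16F10 fit of mononuclear phagocytes unchanged and tests nothing there. Such repeats are counted below among the values that stayed the same. Random gene lists belong to the branch without replicates. Shallow spleen hashtags and 142 cells in MC38 spleen 1 limit what can be seen in spleen. A sign change counts as reversed only where the value passes the threshold in at least 1 of the settings compared.

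Pf4 kept its direction and call in all 25 alternative values, and in 12 of 12 with a hashtag left out. Classical monocyte-like cells alone are not among these values. There Pf4 had no UMI in MC38, and in B16F10 it did not pass the count filter (3.74 without it). Of the named gene values, 5511 of 5812 kept direction and side of the threshold, 191 lost and 90 gained a call, and 20 reversed; with a hashtag left out these were 3036 of 3231, 149, 44 and 2. Of the named genes' interactions 1098 of 1235 were the same, 76 lost and 43 gained a call, and 18 reversed; with a hashtag left out 1093 of 1164, 54, 16 and 1. For single gene lists 421 of 460 were the same (201 of 219 with a hashtag left out), and for class shares 67 of 75 (60 of 60).

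Hashtag rules: the 10 UMI rule left 15 MC38 and 350 B16F10 spleen cells and the 2 UMI rule 688 MC38 spleen cells (1372 and 2730 reported). With the 10 UMI rule, B16F10 genes higher and lower were 1294 and 936 in mononuclear phagocytes and 807 and 781 in T cells, and 1149 were lower in dendritic cells; fewer spleen cells entered. With the 2 UMI rule in MC38, 1295 genes were lower in mononuclear phagocytes, 189 higher and 16 lower in NK cells, and 191 higher and 56 lower in dendritic cells, and the interaction called 562. Normalization within cells gave 161 lower MC38 dendritic genes, with 3 spleen hashtags in the fit in place of 2.

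Thinned cells, with fewer UMIs by construction, gave 1583 higher and 1172 lower genes in MC38 and 1261 and 1119 in B16F10 mononuclear phagocytes, and an interaction count of 396. Total-UMI scaling gave 1673 and 3999 in MC38 and 1608 and 3712 in B16F10 mononuclear phagocytes, 1110 lower in MC38 T cells, 434 and 486 lower in MC38 and B16F10 NK cells, and 1155 higher and 3116 lower in B16F10 dendritic cells. DESeq2 gave 362 lower in MC38 and 930 in B16F10 T cells, 271 higher and 94 lower in MC38 and 293 and 103 in B16F10 NK cells, and 128 and 1115 lower in MC38 and B16F10 dendritic cells. No count filter gave 682 higher in MC38 NK and 721 in MC38 dendritic cells. The looser cell filter gave 428 lower and the removal of the top Scrublet scores 792 higher and 677 lower in MC38 dendritic cells. With either of these, 3 spleen hashtags entered the dendritic fit, against 2 as reported.

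Classical monocyte-like cells alone gave 883 higher and 594 lower genes in MC38 and 1295 and 1077 in B16F10. The interaction count was 41 and the same direction held for 100%, with fewer genes tested in them. Their tumor and spleen cells lay mostly in different clusters, so this setting does not hold the mix of clusters fixed. Lists called lower were then 0 in both libraries. An estimated correlation left 0 higher and 0 lower lists in MC38 and 4 and 0 in B16F10, and no count filter gave 2 lower lists in B16F10.

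With 1 hashtag left out, the share of mononuclear phagocytes in tumor minus spleen ranged from 42.19 to 50.19 points (46.21 reported) in MC38 and 34.86 to 41.03 (38.21) in B16F10. The log2 fold change of Pf4 ranged from 11.57 to 12.14 in MC38, where it depends on the prior count, and 9.343 to 10.25 in B16F10. In mononuclear phagocytes 2007 to 2586 genes were higher and 1385 to 2040 lower in MC38, and 2158 to 2484 and 1873 to 2316 in B16F10. In T cells these were 705 to 995 and 386 to 705 (386 without spleen 2) in MC38 and 1314 to 1815 and 1165 to 1622 in B16F10. In NK cells 192 to 383 were higher (270 without spleen 2, 192 without spleen 3) and 36 to 192 lower (75 and 36) in MC38, and 307 to 476 and 122 to 250 in B16F10 (lower: 174 without spleen 1, 134 without tumor 2, 122 without tumor 3). In dendritic cells 328 to 457 were higher and 99 to 299 lower in MC38 (lower: 115 without spleen 2, 99 without spleen 3), and 1722 to 1972 and 1431 to 1684 in B16F10. Leaving out a spleen hashtag left only 1 in MC38 NK and dendritic cells, and those counts are not given. The named gene values with a hashtag left out do include such fits, where the lone sample is assumed to vary like the others. Lists called higher ranged from 13 to 14 in MC38 and 12 to 15 in B16F10, with 1 lower each time. The interaction count ranged from 538 (without MC38 spleen 2) to 1079, and the same direction from 97.03% (without B16F10 tumor 3) to 98.07%.

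Reversed log2 fold changes in classical monocyte-like cells alone were Ccl6 (0.16), Nr4a1 (0.87), Pglyrp1 (0.71) and Tubb5 (-0.84) in MC38, and Fn1 (-0.41), H2-D1 (0.24), Nr4a1 (0.81), Pglyrp1 (0.34), Tubb5 (-0.22) and Zfp36 (0.51) in B16F10. There the interactions of Cxcl10 (-3.63), Il1b (-1.50), Pglyrp1 (-0.38), Fn1 (-0.34), Nfkbia (-0.33), Nr4a1 (-0.073), Il16 (0.16), H2-Aa (0.10), Bst2 (0.082), Calhm2 (0.041), Cd74 (0.039) and Psmb8 (0.0040) reversed. With the top Scrublet scores removed, MC38 NK Apoe (-1.42), Cd74 (-1.31), H2-Ab1 (-1.15) and H2-Aa (-0.85), MC38 dendritic Psmb8 (0.60), B16F10 NK Hmgb2 (0.51), the interactions of Stmn1 (3.30) and Tubb5 (1.02) and the cell cycle list in MC38 mononuclear phagocytes (down, adjusted p 0.692) reversed. The looser filter reversed MC38 dendritic Ccl5 (1.32), Psmb8 (0.74) and Cfp (-0.11) and the Stmn1 interaction (3.19), and resolution 0.5 the latter (3.26). The 2 UMI rule turned MC38 dendritic Apoe to -0.18, in a fit with only 1 spleen hashtag. Leaving out stray spleen cells reversed the interactions of Cxcl10 (-2.43) and Mmp14 (-7.03, set by the prior count since no MC38 spleen UMI was left), and leaving out MC38 spleen 3 that of Cxcl10 (-2.26, the lowest of a range up to 0.73), since those cells and that hashtag hold most of the spleen Cxcl10. Without B16F10 tumor 2, T cell H2-Aa (-2.40, range up to 0.65) and H2-Eb1 (-2.22, range up to 0.77) reversed. The Cx3cr1 fall in MC38 mononuclear phagocytes lost its call without a count filter (adjusted p 0.0771), with the looser filter (0.291), at resolution 0.5 (0.372), with normalization within cells (0.0769), the 2 UMI rule (0.669), the top Scrublet scores removed (0.367), and without spleen 2 (0.217) or 3 (0.0847).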

Other observations

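The values here were chosen after the report's results were seen, and none but the log2 fold changes at the end was tested. Tumor macrophage-like clusters held Pf4 at unequal levels. In MC38 cluster 14, with Arg1 at 1758 and Mmp12 at 760 CPM, averaged 184.1 ± 73.3 CPM of Pf4 over 3 hashtags, clusters 7, 2, 0 and 5 averaged 100.4, 97.0, 82.2 and 81.4 CPM, and clusters 1, 20 and 15 averaged 32.7, 21.3 and 14.9 CPM. The tumor classical monocyte-like cluster 4 held no Pf4 and had Cxcl10 at 1873 and Cxcl9 at 409 CPM. In B16F10 cluster 2, with Spp1 at 6017 and Arg1 at 2094 CPM, averaged 710.2 ± 293 CPM of Pf4, cluster 6, with C1qa at 2795 CPM, averaged 523.0 ± 179, and the classical monocyte-like cluster 16 averaged 6.69 ± 8.46. Ppbp averaged 35.2 ± 54.9 CPM in B16F10 cluster 2.

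Regulatory T-like cells were too few for a test. Their means weigh each hashtag alike, also hashtags with under 10 cells. In B16F10 only spleen 3 (10 cells) and tumor 2 (26 cells) reached that number, and in MC38 no tumor hashtag did. In MC38, 107 spleen cells averaged 260 ± 88.0 CPM of Cxcr3 and 28.1 ± 4.97 of Tbx21, and 18 tumor cells averaged 146 ± 79.2 and 43.4 ± 52.3. In B16F10, 28 spleen cells averaged 182 ± 63.7 and 17.0 ± 29.5, and 38 tumor cells 232 ± 227 and 67.6 ± 54.7. Ifng averaged 15 ± 13 CPM in MC38 spleen and had no UMI in tumor, where the floor was 38.4 CPM; in B16F10 it averaged 74.0 ± 16 in spleen and 2.96 ± 5.13 in tumor. Classical monocyte-like cells of the tissues lay mostly in different clusters. In MC38, cluster 4 held 201 tumor and 0 spleen cells and cluster 6 held 16 and 223. In B16F10, cluster 16 held 401 and 0 and cluster 12 held 42 and 264. Differences between the tissues in these cells may thus be those of unlike clusters. In classical monocyte-like cells alone Cx3cr1 had a log2 fold change of -1.83 in MC38 and -1.97 in B16F10. That of Cxcl9 was 4.88 and 7.48, and that of Cxcl10 was 6.44 and 2.83. The edgeR adjusted p was under 0.05 for all of these.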
